A study of Escherichia coli with 6 samples.

How the data were processed

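The series holds 6 samples of total RNA from *Escherichia coli* MG1655, a K-12 laboratory strain. The samples fall into 3 groups of 2 by their titles and treatment labels: cells with the empty vector as control, cells labelled BCM, and cells labelled WT Rho plasmid. BCM is the usual short form of bicyclomycin, an antibiotic that inhibits the transcription termination factor Rho, but the labels give only the short form and neither a dose nor a time. Per the labels' protocols, treated cells carried plasmids, and the Rho-treated cells had their chromosomal copy of the gene deleted by P1 transduction, the transfer of DNA by phage P1. Cultures were grown at 37 °C from a 1% inoculum to an optical density (OD600) of 0.4. RNA was extracted with a DNase step, tailed with poly(A) and copied from an oligo-dT primer carrying a T7 promoter. The cRNA was labelled with Cy3 or Cy5, starting from 500 ng of RNA per sample.

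Labelled cRNA was hybridised to a custom Agilent *E. coli* array. The sample descriptions place both samples of a group on 1 array, replicate 1 in Cy3 and replicate 2 in Cy5, so the 6 samples lie on 3 arrays with 1 group on each. Array and group cannot be told apart, and the replicate number is also the dye. Nothing in the labels says that the replicates came from separate cultures, so the p-values below measure only the spread between 2 labelled samples read on the same array, which may be technical.

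The deposited table gives 1 intensity on a linear scale for each of 15204 probes in each sample. Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 11.5. The background correction, the dye normalization, any scaling between arrays and the filters are not given in the sources used here. The values carry no detection or saturation flags, so whether a probe was above background or saturated is unknown, and the fold of a dim probe depends on how the scanner software treats its lowest values. No 2 columns were identical. The number of arrays, not a sequencing depth, limits the precision.

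The table names probes by IDs of 4 families, pCR, NC_A, NC_S and STR, each followed by a number. It does not pair them with genes, and 0 of the 15204 IDs occurred in the RefSeq table of 4651 *E. coli* genes used here. The meaning of the family names is not given in the sources used here. As a result no gene is named, the 38 gene lists fixed before the data were examined (prophages, Rho-attenuated genes, stress and metabolic groups) could not be tested, and rho itself could not be checked. The planned average over the probes of a gene was replaced by a test of each probe. Several probes can belong to 1 gene, so counts of probes are not counts of genes. The rule for named items, fixed before, took the largest differences past the threshold whose samples did not overlap between groups. Without gene names, only the first 2 probes that rose and the first 2 that fell in BCM are printed, with summaries of the rest.

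Intensities were floored at 1, which changed no value, and log2-transformed. The 75th percentiles of the 6 columns spanned 0.17 on the log2 scale, under the limit set beforehand for centring, so the values were used as deposited. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 fit of all 6 samples with 3 residual degrees of freedom, with Benjamini-Hochberg adjustment over the 15204 probes of each of 3 comparisons and a threshold of 0.05. Values are given as mean ± SD of the 2 samples. A probe family was compared with all other probes with limma's camera at an inter-probe correlation of 0.01, adjusted over 12 tests (4 families and 3 comparisons), and again with the correlation estimated from the residuals. The families, the ranges of vector intensity, the tests within such a range and the windows described next were chosen after the data were seen.

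Running medians over 31 pCR probes in the order of their ID numbers were set against the most extreme running median of 100 shuffled orders, and windows beyond it were taken without overlap. The similarity of BCM and WT Rho was set beside 100 simulated unchanged groups compared with the same vector samples. On simulated data made from the 15204 probes for BCM minus vector, with 50 probes changed at each size, the limma step recovered 0%, 42%, 68% and 82% of those changed by 1, 2, 3 and 4 on the log2 scale, with 9 calls among unchanged probes. With so few probes changed, the adjusted threshold is stricter than in BCM minus vector, where 9995 probes passed. These shares therefore check the step and do not give its power in that comparison. For WT Rho minus vector, the window step found 3 of 3 planted windows among the 10655 pCR probes and 0 in a shuffled order. The alternatives were a replicate block, other scalings, a filter on dim probes, other moderation, the 2 compared groups alone, log2(value + 16), a floor of 64, a 2-fold limit, and each sample left out in turn. Figures were drawn with matplotlib 3.10.9.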

Results

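Probe intensities of *E. coli* MG1655 RNA were measured in 3 groups of 2 samples: vector control, BCM and WT Rho, in which plasmid-borne wild-type rho stood in for the deleted chromosomal copy. The median intensity over 15204 probes was 370 ± 4.59 (SD, n = 2) in vector, 852 ± 0.924 in BCM and 390 ± 0.321 in WT Rho. The 75th percentiles lay close together, between 2105 and 2364 in the 6 samples, and were 2129.91 and 2129.93 in the BCM samples. How the columns were scaled is not given. Neither this closeness nor the small SDs of medians here and below can therefore be read as agreement between samples. The low end of the scale differed. Of all probes, 19.7% ± 0.381 had an intensity under 32 in vector and 22.6% ± 0.479 in WT Rho, against 2.88% ± 0.181 in BCM. The spread of log2 intensity over probes was accordingly narrower in BCM, with an SD of 2.20 ± 0.026 against 3.29 ± 0.047 in vector and 3.40 ± 0.073 in WT Rho.

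The 2 samples of a group correlated across probes with Pearson's r of 0.981 in vector, 0.988 in BCM and 0.965 in WT Rho. Between groups, r lay between 0.880 and 0.933 for vector and WT Rho, between 0.710 and 0.742 for vector and BCM, and between 0.641 and 0.679 for BCM and WT Rho. Probes are not independent replicates. WT Rho had the widest spread between its samples: 80.7% of probes lay within 2-fold of each other in its 2 samples, against 89.5% in vector and 97.7% in BCM.

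The 4 probe families had different levels. The 10655 pCR probes had a median log2 intensity of 9.55 ± 0.0092 in vector, 10.13 ± 0.0015 in BCM and 9.78 ± 0.034 in WT Rho (n = 2 each). The 2190 NC_A probes were dimmer, at 5.81 ± 0.071 in vector, 8.38 ± 0.010 in BCM and 5.22 ± 0.010 in WT Rho. The 2190 NC_S probes were similar, at 5.76 ± 0.099, 8.25 ± 0.031 and 5.15 ± 0.047. The 169 STR probes were the brightest, at 15.07 ± 0.17, 13.71 ± 0.13 and 14.34 ± 0.24.

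**Figure D1:**
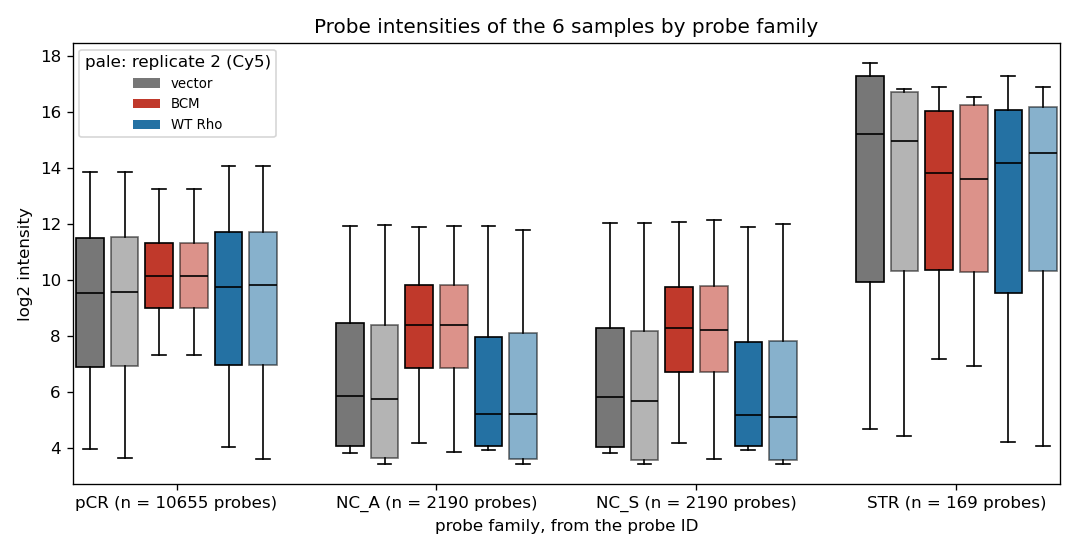
Log2 intensity of the probes in each of the 6 samples, by probe family. Boxes span the quartiles with the median as a line, whiskers the 5th to 95th percentile, and the paler box of each pair is replicate 2 (Cy5). The NC_A and NC_S medians lie near 8.38 and 8.25 in BCM and under 6 in the other 4 samples.

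The comparison of BCM with vector asks how the RNA of cells under BCM differs from that of control cells. Probes dim in vector were brighter in BCM, and probes bright in vector were dimmer. Sorting by the vector values that enter the difference favours this pattern, and a probe near the lowest values can hardly fall. Of the 3110 probes with a mean log2 intensity under 5 in vector, 2592 rose in BCM and 0 fell by limma's adjusted p, with a median log2 difference of 3.61. Its size depends on the floor and the scaling: it was 1.70 with values under 64 set to 64 and 0.73 after quantile normalization. Their median log2 intensity was 3.80 ± 0.28 in vector and 7.71 ± 0.035 in BCM (n = 2). Of the 3870 probes at 11 and over in vector, 2129 fell and 190 rose, and the median log2 difference was -0.91. With the level from vector replicate 1 and the difference from vector replicate 2, the medians were 3.55 under 5 and -0.86 at 11 and over. Both vector samples lie on 1 array, so this split removes only part of the effect of the sorting. The 3809 probes between 5 and 8 had a median difference of 2.27 and the 4415 between 8 and 11 one of 0.17.

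The families differed within these ranges. Among probes under 5 in vector, 1205 of 1251 pCR probes rose in BCM (96.3%), with a median log2 difference of 4.31. In the same range, 679 of 904 NC_A probes rose (75.1%, median 3.02) and 701 of 944 NC_S probes (74.3%, median 2.89). The pCR probes in this range rose more than the others by camera (adjusted p = 4.4e-12), a call not kept with an estimated correlation (adjusted p = 0.83). Among the probes under 32 in both vector samples, 9 of 899 pCR probes (1.00%), 131 of 754 NC_A probes (17.4%) and 142 of 784 NC_S probes (18.1%) were still under 32 in both BCM samples.

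Over all intensities, 1227 of 2190 NC_A probes rose in BCM and 219 fell, with a median log2 difference of 1.55. Of the NC_S probes, 1224 rose and 211 fell, with a median of 1.56. Both families were shifted upward against the other probes (camera adjusted p = 0.0021 and 0.0013), a call lost with an estimated correlation (adjusted p = 0.36 and 0.37). The pCR probes split into 4488 that rose and 2535 that fell, with a median of 0.42, 1.02 below that of the other probes (camera adjusted p = 7.6e-04, and adjusted p = 0.0042 with an estimated correlation). The NC probes were dimmer in vector. At closer vector levels they rose less than pCR probes under 5 and from 5 to 8, and the medians differed less from 8 to 11. From 5 to 8 the median was 2.54 for pCR, 1.84 for NC_A and 1.60 for NC_S. From 8 to 11 it was 0.18, -0.01 and 0.21. At 5 and over, a wide range that leaves differences in level, it was 0.11, 0.66 and 0.71. Both NC families lay above the other probes of that range (camera adjusted p = 0.042 and 0.038, and adjusted p = 0.012 and 0.041 with an estimated correlation). Without the 25% of probes dimmest by their mean over all samples, the pCR, NC_A and NC_S calls made over all probes ended, with medians of 0.06, 0.46 and 0.53. Of the 169 STR probes, 64 fell and 27 rose, with a median of -0.68 (camera adjusted p = 3.1e-07, and adjusted p = 0.36 with an estimated correlation), which was -0.26 without vector replicate 1. With 1 sample left out, the STR median lay between 1.04 and 1.75 below that of the other probes. After quantile normalization, none of the 4 families differed from the other probes by camera, and the medians of log2 difference were -0.26 (pCR), -0.29 (NC_A), -0.30 (NC_S) and -0.09 (STR).

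In all, 9995 of 15204 probes passed the threshold, 6966 higher and 3029 lower in BCM, and 6552 and 2281 of these differed by at least 2-fold. The columns' log2 medians were 1.20 higher in BCM than in vector, and the split depends on that shift. With each column centred on its median, 4572 probes were higher and 6452 lower, the probes under 5 in vector stayed higher by a median of 2.41, and the probes at 11 and over were lower by a median of -2.12. After quantile normalization, 4156 were higher and 5421 lower. Median centring turned the pCR median to -0.78 and left those of NC_A, NC_S and STR at 0.35, 0.35 and -1.89. The count of probes lower in BCM was 1725 without BCM replicate 1 and 1474 without BCM replicate 2.

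**Figure D2:**
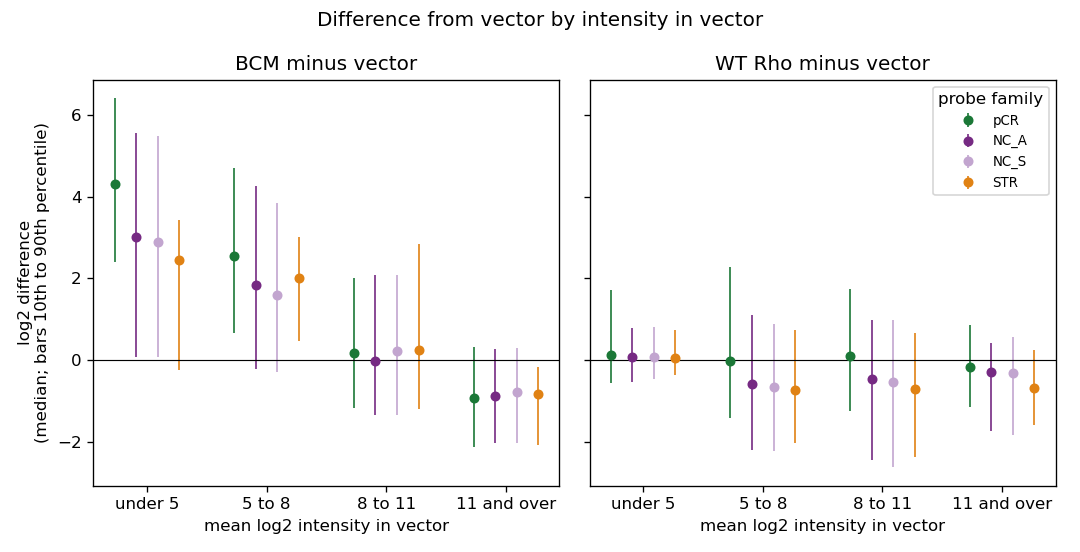
Log2 difference from vector by the mean log2 intensity in vector, for BCM (left) and WT Rho (right). Points are medians over the probes of a family and bars span the 10th to 90th percentile of those probes. In BCM the median over all probes goes from 3.61 under 5 to -0.91 at 11 and over; in WT Rho it lies between -0.24 and 0.09 in every range.

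The 10 largest rises in BCM were between 8.43 and 8.98 on the log2 scale. They belonged to 7 pCR, 2 NC_A and 1 NC_S probes with a median vector level of 3.94, near the lowest values of the table, so the size of a rise depends on that floor. GT_EC_NC_A_1803 had a log2 intensity of 3.68 ± 0.31 in vector, 12.66 ± 0.20 in BCM and 3.75 ± 0.37 in WT Rho, a rise in BCM of 8.98 (SE 0.29, limma adjusted p = 8.8e-05). GT_EC_pCR05647 rose by 8.94 (SE 0.33, limma adjusted p = 8.8e-05), from 4.42 ± 0.22 in vector to 13.37 ± 0.21. With values under 64 set to 64, the rises of these probes were 6.66 and 7.37, both still past the threshold. The 10 largest falls were between -5.42 and -10.41 and belonged to 9 pCR probes and 1 NC_S probe. GT_EC_pCR03484 went from 15.64 ± 0.72 in vector to 5.23 ± 1.01 in BCM, a difference of -10.41 (SE 0.59, limma adjusted p = 1.0e-04), or -9.64 with the floor of 64. GT_EC_pCR03264 went from 17.22 ± 0.71 to 7.90 ± 0.17, a difference of -9.31 (SE 0.39, limma adjusted p = 8.8e-05).

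The comparison of WT Rho with vector asks how RNA differs between cells that make Rho from a plasmid alone and control cells. Of the NC_A and NC_S probes that were not dim in vector, more were lower than higher in WT Rho. Among probes at 5 and over in vector, 353 of 1286 NC_A probes fell and 97 rose, with a median log2 difference of -0.50, and 360 of 1246 NC_S probes fell and 85 rose, with a median of -0.58. In the same range, 1131 of 9404 pCR probes fell and 1394 rose, with a median of -0.05. Both NC families lay below the other probes of that range (camera adjusted p = 4.2e-04 for NC_A and 2.3e-04 for NC_S), also with an estimated correlation (adjusted p = 0.0058 and 0.012). Selecting on the vector values that enter the difference favours falls. Among probes with a mean of vector and WT Rho at 5 and over, 296 of 1205 NC_A probes fell and 111 rose, with a median of -0.35, 307 of 1188 NC_S probes fell and 103 rose, with a median of -0.42, and the pCR median was -0.0081 (camera adjusted p = 0.0026 for NC_A and 0.0014 for NC_S, and adjusted p = 0.0060 for each with an estimated correlation). With probes selected by 1 vector sample and the difference taken from the other, the medians were -0.40 and -0.37 for NC_A and -0.48 and -0.44 for NC_S. The shift below the other probes kept its sign under every scaling and selection tried, but not its size or call. Selected by BCM, which keeps 1980 of the 2190 NC_A probes, the shifts were -0.12 for NC_A and -0.11 for NC_S. With an estimated correlation, selections by BCM and by vector replicate 1 lost both calls. Selection by WT Rho lost that of NC_A. At vector levels from 5 to 8, the median was -0.59 for NC_A, -0.67 for NC_S and -0.03 for pCR. From 8 to 11 it was -0.47, -0.55 and 0.09. Among the 3110 probes under 5 in vector, few of which passed the threshold (207 higher, 19 lower), the median difference was 0.09, against 3.61 in BCM. Its sign rested on single samples, with -0.17 without WT Rho replicate 1 and 0.32 without WT Rho replicate 2.

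Over all intensities the NC shifts were small, with a median of -0.09 for NC_A (camera adjusted p = 0.031, and adjusted p = 0.47 with an estimated correlation) and -0.06 for NC_S (camera adjusted p = 0.042, and adjusted p = 0.52 with an estimated correlation). Without vector replicate 1 the NC_A and NC_S medians lay 0.0043 and 0.10 above those of the other probes, and neither passed the test. Without WT Rho replicate 2, neither these families nor the pCR probes passed (adjusted p = 0.30, 0.40 and 0.17). Of the 169 STR probes, 45 fell and 4 rose, with a median of -0.65 (camera adjusted p = 4.0e-06, and adjusted p = 0.36 with an estimated correlation). The STR median was -1.11 within Cy3 and -0.33 within Cy5. The pCR probes, 1547 higher and 1140 lower, had a median of -0.00064, above the -0.09 of the other probes (camera adjusted p = 0.0058, and adjusted p = 0.0054 with an estimated correlation). Quantile normalization ended this call, and without vector replicate 1 the pCR median minus that of the others turned to -0.018.

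In all, 3694 probes passed the threshold in WT Rho, 1786 higher and 1908 lower, and 1616 and 1721 of these differed by at least 2-fold. With each column centred on its 75th percentile, 1503 were higher and 2425 lower. The count depended on single samples and on the pooled spread. With only the 2 groups compared, which leaves fewer residual degrees of freedom, 1705 probes passed, 910 higher and 795 lower. Pooling takes in the BCM samples, whose difference had an SD over probes of 0.34, against 0.65 in vector and 0.90 in WT Rho. The pooled fit may therefore understate the error of WT Rho minus vector, and with it the SEs and p-values given for it.

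Some changes in WT Rho came in runs of neighbouring pCR numbers. In 16 windows of 31 neighbouring pCR probes the running median lay above, and in 6 below, every running median of the shuffled orders, which stayed between -0.92 and 1.33. In the window that rose most, the median log2 difference was 6.32, or 80.0-fold, and 23 of 31 probes rose. Its median log2 intensity was 8.63 ± 0.14 in vector and 13.35 ± 0.72 in WT Rho. The next windows rose by a median of 3.16 and 2.79, with 31 of 31 probes past the threshold in each. A further window rose by 2.75, but by 4.48 within Cy3 and 0.56 within Cy5, with 11 of 31 probes past the threshold. In the window that fell most the median difference was -3.68, 23 of 31 probes fell, and the median log2 intensity was 12.68 ± 0.082 in vector and 7.65 ± 0.24 in WT Rho. The probes that fell were neighbours, and 5 in a row were at intensities of 72.4 or less in both WT Rho samples. In BCM the window that rose most in WT Rho had a median difference of 1.88 and the one that fell most -1.01.

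**Figure D3:**
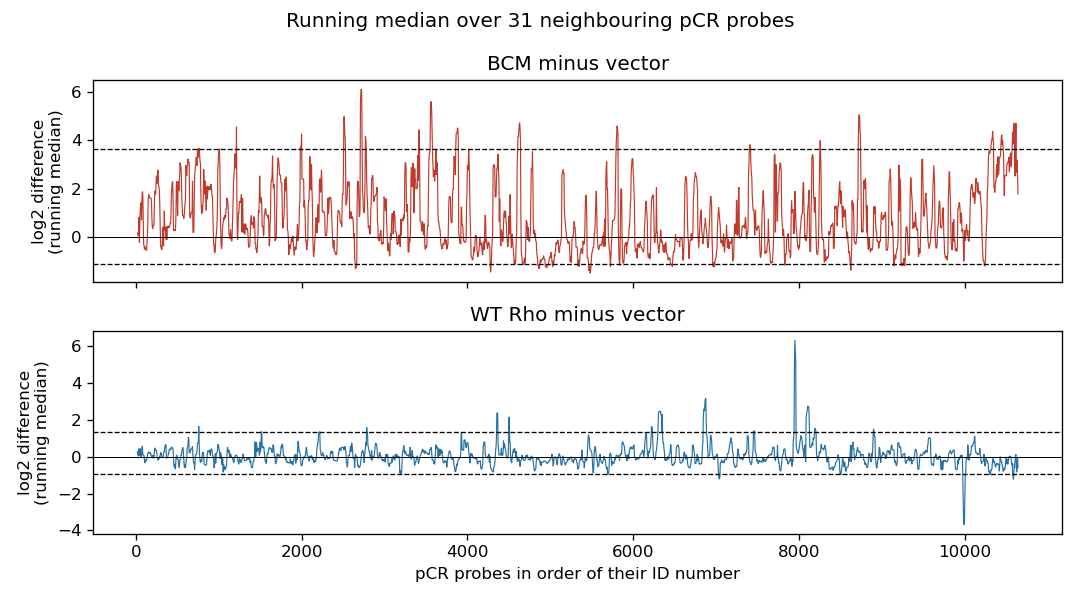
Running median of the log2 difference from vector over 31 pCR probes in the order of their ID numbers, for BCM (top) and WT Rho (bottom). The line is drawn at every 5th position, and dashed lines mark the most extreme running medians of 100 shuffled orders. WT Rho lies near 0 along most of the order, with a window at 6.32 and one at -3.68, while BCM varies along its whole length.

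The BCM comparison also had such windows, 18 above and 20 below the shuffled limits of 3.66 and -1.12. In the highest the median log2 difference was 6.12 and 26 of 31 probes rose, and in the next it was 5.71 and 30 of 31 rose. In the lowest it was -1.51 and 17 of 31 fell. The median vector level was 5.75 in the highest window, 4.91 in the next and 12.37 in the lowest. The shuffled orders take no account of vector level, so these windows may in part follow the change with vector level given above. Log2 differences of pCR probes 1 number apart correlated with r = 0.74 in BCM and 0.68 in WT Rho, and those of probes 100 numbers apart with r = 0.07 and 0.03.

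Of single probes, the 10 largest falls in WT Rho were between -8.41 and -11.52. GT_EC_pCR03484, which had the largest fall in BCM, also had the largest in WT Rho, a difference of -11.52 (SE 0.59, limma adjusted p = 6.7e-04) to a level of 4.11 ± 0.47, or -9.64 with the floor of 64. GT_EC_pCR03264 differed by -8.56 (SE 0.39, limma adjusted p = 4.6e-04). The 10 largest rises were between 9.13 and 9.73, from a median vector level of 4.69, near the lowest values of the table. In 5 of these 10 probes the WT Rho samples differed by more than 4-fold, by up to 14.0-fold, and with values under 64 set to 64 the 10 rises lay between 6.74 and 9.43. GT_EC_NC_A_1803 and GT_EC_pCR05647, which rose in BCM, had WT Rho levels of 3.75 ± 0.37 and 4.58 ± 0.55, close to vector.

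The changes in BCM and in WT Rho were nearly uncorrelated. The log2 differences from vector correlated across probes with Pearson's r of 0.093 and Spearman's rho of 0.054. Unchanged groups simulated against the same vector samples gave an r of 0.50, because the vector samples enter both sides. The simulated differences hold noise alone, so this r and the observed r are not on a like scale. The lower observed r therefore does not show less similarity than between unchanged groups. The covariance was 0.28, against 0.080 in the simulation, a difference of 0.20. When BCM was set against vector replicate 1 and WT Rho against vector replicate 2, r was 0.13, and with the vector samples exchanged it was -0.0093, so a small covariance of either sign is within the spread of the vector samples. The 2 vector samples could not be split into sets of 2, and part of any excess may come from the shared controls. Of the probes that rose, 891 did so in both comparisons, where independent lists would share 818, and 378 fell in both, where independent lists would share 380. BCM rises met WT Rho falls in 892 probes (874 for independent lists), and BCM falls met WT Rho rises in 287 (356 for independent lists). Independent lists take no account of the shared vector samples or of the vector level, so these counts decide nothing about shared changes.

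In the direct comparison of BCM with WT Rho, of 15204 probes 10596 passed the threshold, 7213 higher and 3383 lower in BCM. The NC_A probes were higher in BCM by a median log2 difference of 2.02 (1354 higher, 230 lower) and the NC_S probes by 1.87 (1361 higher, 201 lower). Both exceeded the other probes (camera adjusted p = 1.5e-04 and 1.0e-04, and adjusted p = 0.36 for each with an estimated correlation). Among probes under 5 in vector the order was reversed, with medians of 3.91 for pCR, 2.88 for NC_A and 2.70 for NC_S. At 5 and over in vector, a wide range that leaves differences in level, they were 0.08, 1.22 and 1.29. The pCR probes had a median of 0.38 (4457 higher, 2924 lower), below the other probes (camera adjusted p = 7.9e-06, and adjusted p = 0.0036 with an estimated correlation). The STR probes had a median of 0.00037 (41 higher, 28 lower), which was below the median of 0.81 of the other probes (camera adjusted p = 0.031, and adjusted p = 0.53 with an estimated correlation). Without WT Rho replicate 2 the STR call was lost (adjusted p = 0.088), and without BCM replicate 2 the count of lower probes was 2113. Centred on the column medians, the split was 5029 higher and 6261 lower, with family medians of -0.75 (pCR), 0.89 (NC_A), 0.75 (NC_S) and -1.13 (STR), and after quantile normalization 4584 higher and 5510 lower, with medians of -0.19 (pCR), -0.17 (NC_A), -0.21 (NC_S) and 0.23 (STR). Quantile normalization ended the pCR, NC_A and NC_S calls and turned the STR probes to 0.41 above the others (camera adjusted p = 0.21).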

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

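The scalings and fits were planned before the data were examined; the families, intensity ranges, windows, the floor of 64, the values within a dye, the estimated correlation and the selections of probes were chosen after. Of 438 recomputed values for the comparisons, 366 kept their direction and their side of the threshold, or stayed within 1.5 times a count or 1 SD of a value; 37 family tests lost their call, 1 reversed and 34 values moved further. The 4 named probes and the windows kept theirs in 169 of 170, where a change of sign counted as kept if the main difference did not pass. Such changes occurred: GT_EC_NC_A_1803 in WT Rho minus vector ran from -0.19 to 0.32 with 1 sample left out. These 4 probes were picked as the largest past the threshold, and leaving out a sample of the third group cannot move their differences. Much of this tally could therefore hardly change. With windows of 15 probes, WT Rho had 37 windows in place of 22. The lower NC_A and NC_S shifts among probes at 5 and over in vector, in WT Rho minus vector, passed under every scaling and fit. Selected by vector 1 with the difference from vector 2, the shifts of -0.32 and -0.40 passed, but not with an estimated correlation (adjusted p = 0.10 and 0.12). Nor did the -0.12 and -0.11 of probes selected by BCM (adjusted p = 0.35 and 0.43). Selected by WT Rho, NC_A lost its call at -0.14 (adjusted p = 0.056). The cause of the changes below was not tested, except that fewer samples or groups leave fewer residual degrees of freedom. Replicates of 2 allow no count of other splits. The median over the probes of a gene, the gene lists and fry were not run for lack of gene names, and a floor of 1 changed nothing.

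Same-numbered samples deviated together with r = 0.23 (vector and BCM), 0.094 (vector and WT Rho) and 0.091 (BCM and WT Rho), so they share a number and a dye, not a shown pairing. With a replicate block 9880, 3232 and 10496 probes passed in BCM minus vector, WT Rho minus vector and BCM minus WT Rho, of which 9628, 3111 and 10298 also passed without it.

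Probe counts moved as follows. In BCM minus vector, median centring gave 4572 higher and 6452 lower, quantile normalization 4156 and 5421, and dropping the dimmest 25% of probes 4116 higher. In BCM minus WT Rho, median centring gave 6261 lower, quantile normalization 4584 higher and 5510 lower, and dropping the dimmest probes 4315 higher. With only the 2 groups compared, WT Rho minus vector had 1705 calls, 910 higher and 795 lower. Leaving out 1 sample, which assumes that the lone sample left varies like the other groups, gave 1474 to 3734 lower in BCM minus vector, 1288 to 5686 in WT Rho minus vector (589 to 3064 lower, the rest higher) and 2113 to 3686 lower in BCM minus WT Rho.

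Family shifts are medians minus those of the other probes. Quantile normalization ended every call but that of STR in WT Rho minus vector (-0.51): for pCR, NC_A, NC_S and STR the shifts were 0.014, -0.026, -0.040 and 0.18 in BCM minus vector, and -0.034, 0.0083, -0.036 and 0.41 in BCM minus WT Rho, the last of these reversed; in WT Rho minus vector they were 0.047, -0.033 and -0.0030 for pCR, NC_A and NC_S. Camera's direction and the median differ in sign in some of these. Without the dimmest probes, calls ended at -0.33 (pCR), 0.37 (NC_A) and 0.44 (NC_S) in BCM minus vector and -0.25 (STR) in BCM minus WT Rho. With an estimated correlation, calls ended for NC_A, NC_S and STR at unmoved shifts of 0.95, 0.97 and -1.45 (BCM minus vector), -0.067, -0.037 and -0.62 (WT Rho minus vector) and 1.40, 1.26 and -0.81 (BCM minus WT Rho). In WT Rho minus vector, the floor of 64 put the NC_A and NC_S shifts at 0, and 75th percentile centring left NC_S at -0.037, past the threshold no longer. With 1 sample left out, shifts there ranged from -0.018 to 0.23 (pCR), -0.15 to 0.0043 (NC_A), -0.14 to 0.10 (NC_S) and -0.81 to -0.38 (STR), and STR in BCM minus WT Rho from -0.91 to -0.77.

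For probes under 5 in vector, the median rise in BCM was 2.41 with median centring, 0.73 after quantile normalization, 2.74 on log2(value + 16), 1.70 with the floor of 64, 3.44 within Cy3, and 3.46 to 3.71 with 1 sample left out. For probes at 11 and over it was -2.12 with median centring and -0.59 after quantile normalization in BCM, and -0.35 with 75th percentile centring and -0.079 within Cy5 in WT Rho. Without flags, the signal over background that limits dim probes is unknown.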

Other observations

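The NC_A and NC_S families each hold 2190 probes, and probes of the same number in both families were weakly related. In 799 of the 2190 pairs both members rose in BCM, against 686 expected if the members were independent. Most of this excess goes with the members' shared vector level: among pairs of the same vector levels, in 10 ranges per family, 771 were expected, and 1000 shuffles within them gave 748 to 797 (one-sided permutation p = 0.0010, the smallest they can give). In 428 pairs only the NC_A member rose and in 425 only the NC_S member. The BCM levels of the members correlated weakly and negatively (r = -0.14, permutation p = 1e-05, the smallest the permutations can give, also in the vector and WT Rho tests), while their vector levels and WT Rho levels correlated positively (r = 0.095 and 0.10). Pairs are not independent replicates.

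8 probes fell by at least 16-fold in both BCM and WT Rho, 7 of them pCR probes, with a median vector level of 15.70 on the log2 scale, and 55 rose by at least 16-fold in both, with a median vector level of 4.80. Lists shuffled 1000 times among probes of the same vector level shared 0 to 3 falls and 18 to 50 rises. The vector samples lie on 1 array and enter both comparisons, so a high reading there alone would give a fall in both and a low reading a rise in both, and neither count separates this from shared changes. Between the samples of a group, 695 probes differed by more than 4-fold in WT Rho, 290 in vector and 51 in BCM.

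All tests in this part were chosen after the results were seen. The first pattern is the rise of dim probes in BCM. A constant background added to every spot of the BCM array would leave these probes at about 1 level, but among pCR probes under 32 in both vector samples the 90th percentile of BCM intensity was 16.05 times the 10th. Genomic DNA would light all loci about alike, but BCM levels of dim pCR probes 5 numbers apart correlated (r = 0.4637, above the 0.194 of the highest shuffled order), which argues against DNA as the whole source for the pCR probes. For NC_A and NC_S the values go both ways. Same-number pairs dim in vector had correlated BCM levels (r = 0.1154), as DNA would give if a number named 1 place, itself a hypothesis. But over all pairs r was -0.14. Of the probes under 32 in both vector samples, 131 of 754 NC_A and 142 of 784 NC_S probes stayed there in BCM. These values leave DNA open. The RNA was treated with DNase, tailed with poly(A) and copied from an oligo-dT primer, and whether any DNA was labelled was not tested. A difference between arrays cannot be told apart from BCM, because each group has 1 array, and more read-through transcription under an inhibitor of Rho may be the biological source, untested here without gene positions.

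The second pattern is the lower level of STR probes in both treated groups. STR probes are bright, and bright probes fell in BCM: set against pCR probes of the same vector level, they were 0.2562 higher in BCM (bootstrap interval 0.112 to 0.354), so their brightness may account for the fall there. In WT Rho they were lower than matched pCR probes by a median of -0.5719 (bootstrap interval -0.751 to -0.434), which brightness alone would not give in these samples if the matches are close. Both intervals are over 142 STR probes, which are not independent replicates, and do not measure the spread between samples or arrays. Of the probes at 11 and over in vector, the median level was 16.92 for STR and 12.35 for pCR. How close the matches of the brightest STR probes were, and how often a pCR probe was reused, is not given. The unmatched STR median in WT Rho was -1.11 within Cy3 and -0.33 within Cy5. Between BCM and WT Rho 41 STR probes rose and 28 fell, so the median of 0.0003746, which was -1.13 with median centring, decides nothing. A vector array on which these probes were bright cannot be told apart from a change in both treatments, as vector has its own array.

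The third pattern is the joint change of neighbouring pCR numbers in WT Rho. The tables argue against a chance order of the probes, since 22 windows lay beyond every shuffled order. Shuffling single probes would also break up several probes of 1 gene, so this shows only that neighbouring numbers change together. The differences correlated with r = 0.68 at 1 number apart, 0.24 at 5 and 0.08 at 20. In the window that fell most, 8 probes kept at least 50% of their vector intensity, so a loss of DNA, by a deletion or a P1-transduced segment, would not span all 31 probes. The width of 31 was set here and the 23 that fell form 1 run, so this says nothing about a shorter loss. For the 23 neighbouring probes that fell, such a loss cannot be told apart from lower transcription. They kept at most 24.81% of their vector intensity, 0 were under 32 in both WT Rho samples and 6 under 100. Without flags the signal of a probe with no target is unknown, so these levels do not decide. Changed transcription of 1 gene with several probes or of neighbouring genes, a difference in the strain background and a difference between the arrays stay open and untested.

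A further hypothesis is that the same number in NC_A and NC_S names the same place, possibly its opposite strands. The correlation of BCM minus vector at the same number (r = 0.2645) lay above that at each of 100 shifted numbers, which ranged from -0.058 to 0.066. That of WT Rho minus vector (r = 0.041) lay within its range of -0.056 to 0.068, so the hypothesis rests on the change in BCM and on the vector and WT Rho levels. This is consistent with a shared place, and the meaning of the names remains unknown.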
